A study of Mus musculus with 24 samples.

How the data were processed

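Single-cell RNA was measured with droplet 3′ libraries in 24 samples of dissociated mouse cortex, in 4 groups of 6 mice that carried the 5xFAD amyloid transgenes on a C57BL/6 background. Every mouse also carried a tamoxifen-dependent Cre at Cx3cr1 and an inducible TREM2 transgene, either with the common sequence (WT) or with the R47H substitution. Induced mice received tamoxifen at birth and control mice received the oil vehicle. The replicates of a group are separate mice, by the design text 3 males and 3 females, with 1 library each. Per the labels, cells came from perfused, enzymatically dissociated tissue after removal of myelin, red blood cells and dead cells.

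The deposited matrices hold raw UMI counts, 31053 genes per sample, with no normalization. Cell Ranger 3.1.0 is named per the file headers, and the mm10 build (GRCm38) and Seurat 3.1 by the submitters' processing notes. The deposited counts cover 232618 barcodes that the authors kept, 6967 to 11681 per sample. Coordinates are 1-based and come from GENCODE M21, which held 30934 (99.6%) of the gene identifiers. The feature list holds no human transgene. Transcripts of an induced human TREM2 could therefore be counted only where reads aligned to mouse Trem2. Clec7a, 1 of the 33 late DAM list genes, is not in the feature list either.

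Cells with at least 500 genes and at most 15% mitochondrial UMIs were kept, which left out 12344 barcodes and kept 220274. Doublets were scored against simulated doublets by the 30 nearest neighbours, and the highest-scoring 0.8% of cells per 1000 barcodes were removed, 17310 cells or 7.86%. For clustering, 2000 cells per sample, 2000 variable genes without mitochondrial and sex-linked genes, 30 principal components and a shared-neighbour graph (k = 20) were used with the Leiden method at resolution 1. The remaining cells were assigned by their 15 nearest neighbours. A cluster took a class name when at least 3 markers, and at least 50% of that class's markers, were at least 1 log2 unit above the mean of clusters and seen in at least 20% of its cells. A cluster in which a second class reached 85% was left unnamed. This gave 38 clusters, 14 named classes and 4 unnamed clusters. Classes are called "-like" because the names rest on markers alone.

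UMI counts were summed per sample and class, since cells of a mouse are not replicates. The sums were tested with edgeR quasi-likelihood fits (TMM factors, filterByExpr, robust) over all 24 samples with 1 mean per group and 5 contrasts. These were WT induction, R47H induction, the difference of both induction effects, and R47H against WT in induced and in control mice. Adjusted p values are by Benjamini-Hochberg within a contrast, with a threshold of 0.05, and all edgeR tests are two-sided. Classes with at least 20 cells in at least 5 samples of every group were tested, 10 in all. The edgeR, list and share tests, the gene lists, the markers and the alternatives were fixed before the data were examined, apart from additions that are named as such. The 23 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists and contrasts within a class, beside camera with an estimated correlation and fry.

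Genes were named by a rule. For each contrast in microglia-like cells it took Trem2 and, among genes with an adjusted p under 0.05 and a mean of at least 10 CPM, the 10 highest and the 10 lowest by log2 fold change, without sex-linked genes and symbols of the Gm and Rik kinds. It added up to 4 members with the smallest p of each list that passed. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passing. In the other classes the rule took up to 3 genes each way per induction contrast. Other genes named in the text were chosen after their values were seen, and are said to be so. Levels are CPM from edgeR, the summed counts over TMM-scaled totals, as mean ± SD over mice.

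Shares of cells per class were compared with exact two-sided permutation tests (924 regroupings of 6 against 6), and the difference of induction effects with 100000 permutations. None of these tests paired the mice. For shares of cells high in a list, each cell was thinned to 1000 UMIs, and a cell counted as high at a number of list UMIs that at most 5% of control cells reach. Positions of calls were compared with 10000 random gene sets in windows of 10 Mb, a test added after the calls were seen.

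The title numbers of the samples form 6 sets with 1 mouse of each group, and the labels do not say what a set shares. The pairing was checked on 5982 genes with a mean above 20 CPM, by correlating each sample's deviation from its group mean with those of the other group. For WT induction the correlations within sets were 0.21, 0.60, 0.40, 0.39, 0.28 and 0.27, and for induced R47H against induced WT 0.27, 0.44, 0.22, 0.30, 0.23 and 0.38, in each case with the own set as best partner. For R47H induction 2 of 6 sets, and for the control mice 4 of 6, had the own set as best partner. Sexes read from Xist and Y-linked genes gave 3 males and 3 females per group, with sets 1, 3 and 5 male in every group.

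Alternatives were DESeq2, RLE size factors, no low-count filter, a filter of at least 10 CPM in 6 samples, only the groups of a contrast, title sets as a replicate block, a sex term, no doublet removal, a stricter cell filter (1000 genes, 5% mitochondrial UMIs), Leiden resolution 0.5, an ambient RNA filter, sums thinned to equal totals, thinning to 2000 UMIs, a 1% limit for high cells, an estimated correlation, and each sample left out in turn. A fit without 2 libraries with many interferon-high cells, R47H control mouse 4 and R47H induced mouse 5, was added after seeing the data. So was a contrast averaging both inductions. On simulated data for WT induction, 60.6% of 66 genes shifted by 0.5 (log2), 86.6% of 67 shifted by 1 and 96.9% of 65 shifted by 2 were recovered, and 7 of 12671 unshifted genes were called, 4.17% of calls. The simulated counts were drawn for each gene on its own, without effects of title sets, correlation between genes or outlying mice. These shares may therefore not hold for the measured counts.

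Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.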

Results

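Gene expression was measured in single cells of dissociated cortex from 24 mice of the 5xFAD line, which deposits amyloid, at an early amyloid stage. The mice carried an inducible transgene for the microglial lipid receptor TREM2, either in its common form (WT) or with R47H, a substitution linked to Alzheimer's disease risk. There were 4 groups of 6 separate mice, here called WT control, WT induced, R47H control and R47H induced. Induced mice had received tamoxifen at birth, so each induction comparison holds the effect of tamoxifen and of Cre as well as that of the transgene. Between 6967 and 11681 barcodes and between 47478455 and 64210218 UMIs were counted per sample. The median barcode of a sample held 3549.5 to 5984 UMIs and 1647 to 2390 genes, with 3.99% to 5.69% of UMIs mitochondrial. After filtering and doublet removal 202964 cells remained, of which 99178 (48.9%) were microglia-like, 56834 (28.0%) astrocyte-like and 20968 (10.3%) endothelial-like. Microglia-like cells numbered 3294 to 5924 per sample and held 17174129 to 25334472 UMIs per sample, which is the depth behind their values. In these cells 12969 genes were tested.

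The first question was what the mouse reference shows of the transgene. Trem2 (ENSMUSG00000023992, GRCm38 chromosome 17:48346401-48354147) was at 1875 ± 229.5 CPM (SD, n = 6) in WT control, 1739 ± 44.3 in WT induced, 2252 ± 341 in R47H control and 1865 ± 353 in R47H induced microglia-like cells. It passed in none of the 5 contrasts. Its log2 fold change was -0.11 (SE 0.11) with WT induction and -0.27 (SE 0.11, edgeR adjusted p = 0.542) with R47H induction, and 0.10 for R47H over WT in induced mice. That last value became -0.0022 without R47H induced mouse 1. A gain of Trem2 counts with induction was thus not seen in either line, and human TREM2 has no feature in the counts. Among genes that passed in both lines, the smallest adjusted p was that of Setd5 (ENSMUSG00000034269, 6:113077365-113153435), which encodes a SET-domain chromatin protein. Setd5 rose from 103 ± 8.26 to 196 ± 17.6 CPM in WT mice and from 109 ± 9.24 to 175 ± 17.1 in R47H mice. Thumpd3 (ENSMUSG00000030264, 6:113046225-113068273), which encodes a tRNA methyltransferase, lies on the other side of Gt(ROSA)26Sor, the locus widely used for inserted transgenes. It rose from 54.8 ± 4.07 to 76.9 ± 8.68 CPM in WT mice, and its change in R47H mice, 0.24, did not pass (adjusted p = 0.260). Gt(ROSA)26Sor (6:113067428-113077333, opposite strand) overlaps the end of Thumpd3. The insertion site of the transgene is not given in the sources used here. App, also part of the model, was at 128.6 to 138.7 CPM in the group means.

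**Figure D1:**
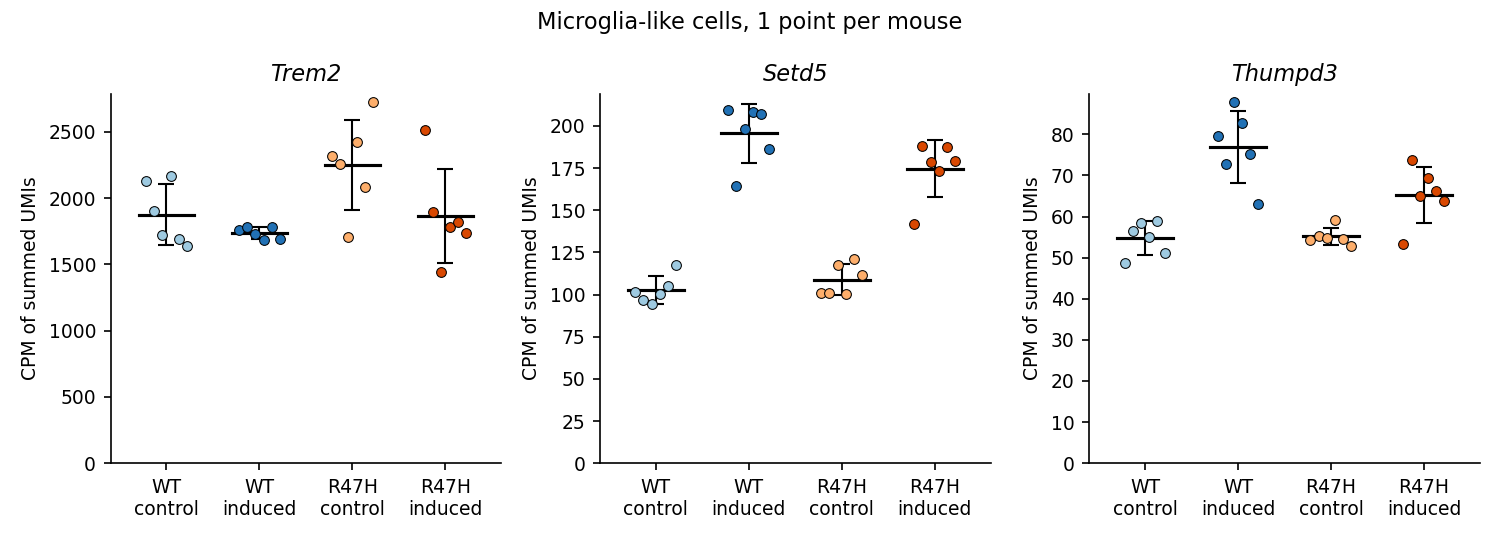
CPM (counts scaled to the summed UMIs of the class) of Trem2, Setd5 and Thumpd3 in the microglia-like cells of each mouse (points) by group, with the mean and SD (n = 6 mice). All Setd5 values of induced mice, from 141.8 CPM upward, lie above the control means of 103 and 109, while the groups overlap for Trem2.

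Induction of the WT transgene asked which genes of microglia change when the common form is switched on. In WT mice 6 genes were higher and 16 lower with induction at an adjusted p under 0.05 in edgeR, out of 770 with an unadjusted p under 0.05. Besides Setd5 (log2 fold change 0.93, SE 0.07, adjusted p = 5.5e-08), Slc29a3 (ENSMUSG00000020100, 10:60712072-60752794), a lysosomal nucleoside transporter, rose from 249 ± 24.8 to 361 ± 10.1 CPM (0.54, SE 0.07, adjusted p = 0.000249). Thumpd3 rose by 0.49 (SE 0.07) and Pxdc1 by 0.99 (SE 0.19), from 16.2 ± 6.64 to 32.1 ± 4.65 CPM. Ccdc66 fell from 21.4 ± 4.63 to 12.5 ± 1.96 CPM (-0.77) and Zfp992 from 14.3 ± 2.39 to 9.62 ± 0.961 CPM (-0.57). Ang, which encodes the ribonuclease angiogenin, was at 144 ± 75.2 and 49.5 ± 7.02 CPM (-1.54, SE 0.31, adjusted p = 0.0473), and the lipase gene Liph at 25.6 ± 8.46 and 12.2 ± 2.50 CPM (-1.07, adjusted p = 0.0284). With the title sets as a replicate block neither passed, at -1.47 (adjusted p = 0.0679) and -1.06. With 1 mouse left out Ang passed in 4 of 24 fits, those without WT control 2 or 4 or R47H induced 3 or 4. Liph passed in 15, and not without WT control 1, 2, 3 or 5 or WT induced 1, 2, 3, 4 or 6. Ang belongs to a family of near-identical genes, so its counts are uncertain. Each of these 8 genes lay beyond the control mean in all 6 induced mice. Of the calls below 10 CPM or outside the naming rule, chosen after the values were seen, Loxl3 fell from 4.50 to 2.25 CPM, Dlc1 by 0.99 (log2) and Vangl1 by 0.95.

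Of the 23 gene lists, 5 passed in WT induction with camera at its preset correlation. The late list of disease-associated microglia (DAM), genes that microglia near plaques raise, had a median of -0.37 over 32 genes, 27 of them below 0 (adjusted p = 2.6e-07). None of its genes passed over all genes tested, and 0 passed when adjusted over the list alone. Cst7, a cystatin of activated microglia, was at 105.0 ± 99.7 CPM in WT control and 24.2 ± 19.2 in WT induced mice, and Igf1 at 17.8 ± 21.7 and 4.06 ± 2.99 CPM. A microglia-like cluster with high Cst7 and Lpl, cluster 10, made up 8.19% and 11.08% in WT control mice 1 and 4. In the other WT control mice it made up at most 5.12%. All 10 early DAM genes were lower (median -0.21), among them Apoe, at 1711 ± 1116 CPM without and 948 ± 251.5 CPM with induction, and the cathepsin gene Ctsd, at 8846 ± 1296 and 7316 ± 350.5 CPM. Lysosome genes had a median of -0.13, with 27 of 30 below 0, though Ctsh was higher by 0.25. Proliferation genes had a median of -0.42, with 18 of 21 below 0, such as Stmn1 at -0.42 and Mcm3 at -0.29, and of -0.75 with the replicate block. Mitochondrially encoded genes passed only with that block (0.10). Interferon-response genes had a median of 0.22, with 26 of 34 above 0. Among them Sp100, at 7.80 ± 2.55 and 20.2 ± 2.77 CPM, passed when adjusted over the list alone and not over all genes. Homeostatic microglia genes had a median of -0.05 and did not pass. No list in any of the 5 contrasts passed with an estimated correlation, where each list that had passed at the preset one had an adjusted p = 0.840 with an estimated correlation. With fry no list passed by direction (smallest adjusted p = 0.290), and 1 passed for change in either direction, immediate early genes between control lines (adjusted p = 0.0285).

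Calls of WT induction fell more often close together than random sets of genes. A stretch of chromosome 14, 50870324-52163546, held 4 of the 22 calls among 21 tested genes, as many as in 72 of 10000 random sets (one-sided permutation p = 0.0073). It holds the Ang family, and the calls in it were Gm26782, Rnase12, Ang and Rpgrip1. Rpgrip1 was also the 1 call of WT induction in astrocyte-like cells, where it fell. Without WT induced mouse 3 the 22 calls in microglia-like cells fell to 9, and without WT induced mouse 6 to 12.

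Induction of the R47H transgene asked the same of the risk form. In R47H mice 19 genes were higher and 18 lower, out of 940 with an unadjusted p under 0.05. Setd5 rose by 0.68 (SE 0.07, adjusted p = 2.6e-05) and Slc29a3 by 0.37, from 267 ± 20.4 to 344 ± 31.9 CPM. F11r (ENSMUSG00000038235, 1:171437535-171464603), which encodes junctional adhesion molecule A, rose from 222 ± 49.5 to 406 ± 65.4 CPM (0.87, SE 0.11, adjusted p = 0.000418). Among called genes of at least 10 CPM, the highest fold change was that of Pttg1 (ENSMUSG00000020415, 11:43420250-43426251), which encodes securin, from 5.75 ± 2.52 to 29.99 ± 21.2 CPM (2.38, SE 0.42), higher than the control mean in 5 of 6 induced mice. Hjurp, a chaperone of centromeric histone, rose from 17.03 ± 8.70 to 47.6 ± 10.4 CPM (1.48), Olfml2b from 12.3 ± 5.54 to 25.2 ± 3.19 CPM (1.03) and Uap1 from 20.1 ± 3.88 to 33.3 ± 5.49 CPM (0.73). Smaller rises were those of Nit1 (0.33) and Dedd (0.30). Pqlc1 was higher by 1.18 (adjusted p = 0.0393), a call that held in 4 of 24 fits with 1 mouse left out, those without WT control 3, 5 or 6 or R47H induced 2.

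Igsf8 (ENSMUSG00000038034, 1:172261641-172319841), an immunoglobulin-superfamily membrane protein gene, fell from 146 ± 25.6 to 67.3 ± 27.5 CPM (-1.12, SE 0.18, adjusted p = 0.00506). Slamf8, a late DAM gene, fell from 87.8 ± 18.3 to 27.2 ± 21.96 CPM (-1.69, SE 0.35). Acadl (ENSMUSG00000026003, 1:66830839-66863277), which encodes the mitochondrial long-chain acyl-CoA dehydrogenase, fell from 33.3 ± 4.21 to 23.02 ± 1.75 CPM (-0.53, SE 0.07, adjusted p = 0.000497). Pea15a fell by 0.67, Cnn2 by 0.63, Tagln2 by 0.53, Cndp2 by 0.46, and the stress-response regulator Atf6 by 0.39. Nbea was lower by 0.47 (adjusted p = 0.0384), a call that held in 9 of 24 fits with 1 mouse left out, those without WT control 1, 3, 5 or 6, WT induced 2, 3 or 6, R47H control 4 or R47H induced 3, and that ended with summed counts thinned to equal totals (0.44, adjusted p = 0.0608) and with only the 2 groups fitted (adjusted p = 0.168). The cystatin C gene Cst3, among the most abundant transcripts of microglia, fell by 0.37 (SE 0.07, adjusted p = 0.0134), in all 6 induced mice. Chosen after the values were seen, Cdkn2a rose from 1.92 to 9.003 CPM (2.23), while Loxl3 (-0.89), Dlc1 (-1.07) and Vangl1 (-0.74) fell as in WT mice.

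Chromosome 1 held many of these genes. A stretch of 1:168119364-173599274 held 15 of the 37 calls among 69 tested genes, against at most 6 in 10000 random sets of genes (one-sided permutation p = 0.0001, the smallest possible). They included Uap1, Olfml2b, Atf6, Cfap126, Dedd, Nit1, F11r, Copa, Pea15a, Igsf8, Tagln2, Cfap45, Slamf8 and Ifi213. The spread of Igsf8 between R47H induced mice was wide: 3 mice were at 42.9 to 49.6 CPM, within or near the WT range of 42.5 to 54.0, 1 at 58.4, and the other two at 99.6 and 104.5, near the R47H control range of 106 to 185.

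**Figure D2:**
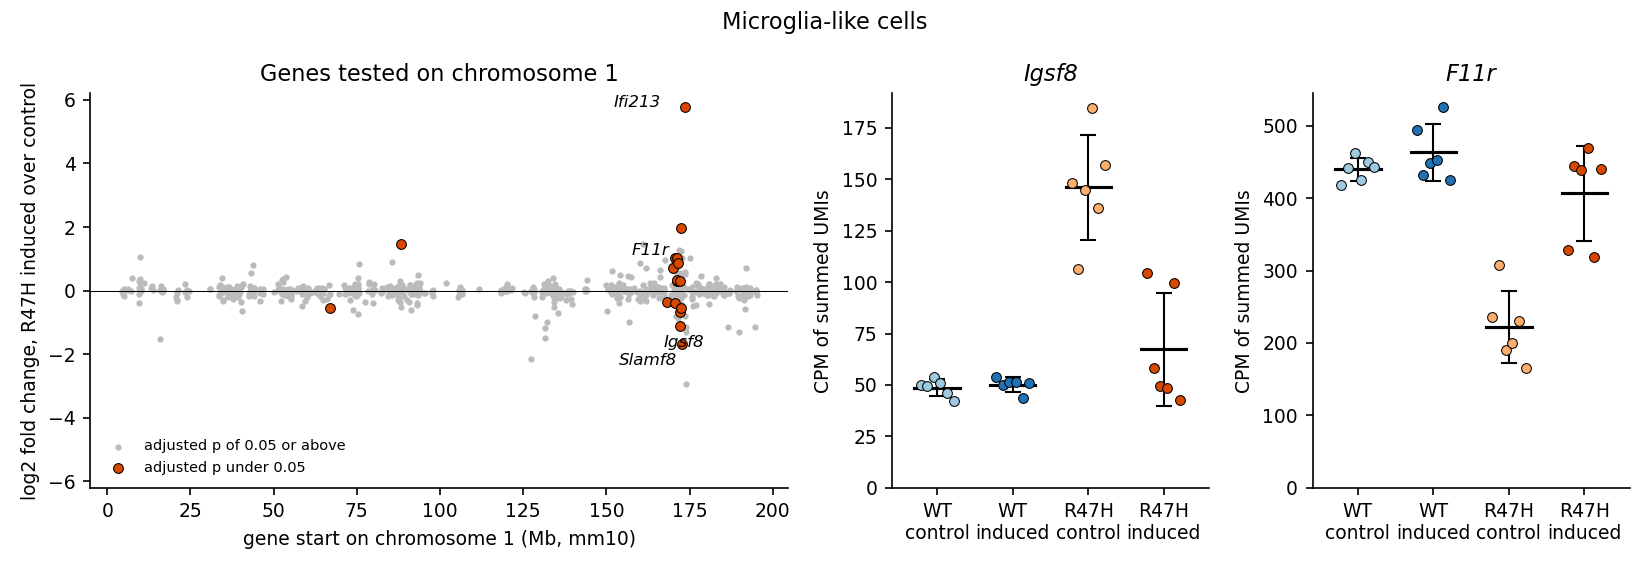
Log2 fold change of R47H induction in microglia-like cells against position on chromosome 1 (megabases, 757 tested genes, genes passing marked), and CPM of Igsf8 and F11r per mouse (points) with the mean and SD (n = 6). Passing genes gather at 168 to 174 megabases, and R47H induced mice spread between the levels of WT mice and of R47H control mice.

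Late DAM genes were lower in R47H induced mice, with a median of -0.65 and 32 of 32 below 0 (camera adjusted p = 8.1e-19, and adjusted p = 0.840 with an estimated correlation). Only Slamf8, which lies in the chromosome 1 stretch and also differed between the control lines, passed over all genes tested. When adjusted over the list alone 8 passed, all lower. Cst7 was at 195 ± 180 CPM without and 64.7 ± 41.0 CPM with induction, Cadm1 at 152 ± 51.0 and 100.1 ± 16.1, and Ccl6 at 236 ± 137 and 103.6 ± 32.5. A microglia-like cluster with high Cst7 and Lpl, cluster 10, was unevenly spread over the R47H control mice. It made up 10.89% and 16.75% in mice 4 and 6 and at most 6.02% in the others. All 10 early DAM genes were lower (median -0.33, 3 adjusted over the list alone), including Tyrobp (-0.36), the adaptor of the receptor, and Apoe, at 2759 ± 1732 and 1428 ± 653 CPM. Cytokine and NF-kB genes had a median of -0.34, with 15 of 19 below 0. Il1b was at 226 CPM and then 119.1 CPM, and Ccl2 at 194 ± 16.3 and 136 ± 41.1 CPM. Lysosome genes were lower (median -0.16, 26 of 30), with Ctsb at -0.34 and Lamp2 at -0.22. Interferon genes had a median of -0.35, with 30 of 34 below 0, such as Cxcl10 (-1.04), though Sp100 was higher by 0.91. R47H control mice 4 and 6 had the most interferon-high cells, 8.52% and 6.63%. Without R47H control mouse 4 and R47H induced mouse 5 the median was -0.27 and still passed. No fit left out both control mice. Ribosomal protein genes (median -0.09, 72 of 76 below 0) and respiratory chain genes (-0.07, 57 of 65) were slightly lower. The list of reactive astrocyte genes (-0.34, 12 of 17) was lower, with C3 at -2.13 and Cp at 1.92. Cholesterol synthesis genes were higher, with a median of 0.15 and 15 of 20 above 0, such as Insig1 at 0.49.

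Lists that did not pass in R47H induction had medians near 0 or wide spreads. Their medians were -0.03 for homeostatic genes, -0.05 for complement, -0.06 for lipid efflux and storage, -0.09 for glycolysis, 0.05 for TREM2 signalling, and 0.03 for myelin. They were -0.19 for disease oligodendrocyte genes, 0.03 for endothelial activation and 0.05 for the blood-brain barrier. TREM2 signalling genes had a mean of -0.005 beside that positive median, and endothelial activation genes a mean of -0.23. The medians of MHC class I and class II genes were -0.22 and -0.52, that of proliferation genes -0.21, that of mitochondrially encoded genes -0.05 and that of immediate early genes 0.04. Without R47H induced mouse 6 the count of calls fell from 37 to 19, and without R47H control mouse 6 to 21.

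Whether the induction effect differed between the forms was tested as WT minus R47H. No gene passed in edgeR, where 370 of 12969 genes had an unadjusted p under 0.05, fewer than chance alone gives. DESeq2 called 14. The genes with the smallest p were Acadl at 0.59 (SE 0.10) and Ppp1r3b, a glycogen-targeting phosphatase subunit, at -0.66 (SE 0.12), both with an adjusted p of 0.0781. F11r (-0.80), Ccdc66 (-0.89) and Zfp992 (-0.65) followed. Setd5 and Thumpd3 both differed by 0.25, which did not pass. Interferon genes had a median difference of 0.65, with 33 of 34 above 0 (camera adjusted p = 5.3e-11), being higher with WT and lower with R47H induction, and an adjusted p of 0.840 with an estimated correlation. Late DAM genes had a median of 0.17, with 26 of 32 above 0, and 1 of them, Slamf8 in the chromosome 1 stretch, passed adjusted over the list alone. Respiratory chain genes (0.09), ribosomal protein genes (0.10), cytokine and NF-kB genes (0.18), mitochondrially encoded genes (0.15) and reactive astrocyte genes (0.22) passed too. The interferon difference was moved by R47H control mice 4 and 6, whose microglia-like cells were interferon-high in 8.52% and 6.63%. In a fit without R47H control mouse 4 and R47H induced mouse 5 it was 0.47 and still passed with camera. R47H control mouse 6 stayed in that fit.

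Both inductions shared 5 calls, Setd5 and Slc29a3 upward and Dlc1, Loxl3 and Vangl1 downward, against 0.0628 expected by chance, and no gene passed in opposite directions. The log2 fold changes of the inductions had r = 0.379 across 12969 genes and r = 0.476 across 7949 genes with at least 10 CPM. These correlations are across genes, which are not independent replicates. The pair of comparisons has no sample in common.

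Induced mice of both lines were compared to find how microglia with the risk form differ from those with the common form. In induced mice 154 genes were higher and 155 lower in R47H, out of 1609 with an unadjusted p under 0.05, and a fit with the sets of consecutive title numbers as a replicate block called 579 in place of 309. Acadl was lower, at 45.1 ± 2.22 CPM in WT and 23.02 ± 1.75 in R47H mice (-0.97, SE 0.07, adjusted p = 8.0e-09). The acetyltransferase gene Kat2b was at 31.3 ± 5.77 and 15.96 ± 1.35 CPM (-0.97), the early-endosome GTPase gene Rab5a at 127 ± 19.03 and 67.7 ± 4.28 CPM (-0.91), and the tensin gene Tns1 at 54.2 ± 2.85 and 28.7 ± 9.08 CPM (-0.92). Upk1b (-1.30), Gpr160 (-0.92), Cep162 (-0.85), Cbr3 (-0.82) and Cables1 (-0.81) were lower as well. Ccdc80 (ENSMUSG00000022665, 16:45093402-45128077), which encodes an extracellular matrix protein, was higher, at 2.45 ± 0.507 and 18.1 ± 5.83 CPM (2.88, SE 0.29, adjusted p = 7.4e-06). Tagap was at 36.7 ± 12.4 and 154.5 ± 87.9 CPM (2.08), Glrp1 higher by 1.55 and Hddc3 by 1.45. Ang (1.62), Rnase6 (1.47), Rnaset2b (3.26), Tpm3-rs7 (4.41), Bcl2a1d (2.48) and, on the lower side, Bcl2a1b (-1.03) belong to families of near-identical genes, and their counts are uncertain. Iglc1 had a fold change of 8.69, which rested on R47H induced mouse 3 and was 0.86 without it. With the replicate block neither Iglc1 nor Rnase6 passed.

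Immediate early and stress genes were lower in induced R47H mice, with a median of -0.29, 18 of 19 below 0 and 3 adjusted over the list alone (camera adjusted p = 1.0e-07, and 0.840 with an estimated correlation). Junb was at 4675 ± 500 CPM in WT and 3829 ± 200 in R47H mice, and Atf3 at 1970 ± 351 and 1514 ± 226 CPM. The tissue was enzymatically dissociated, and what dissociation adds to these genes, or to the cytokine and NF-kB genes below, was not tested. Cytokine and NF-kB genes were lower (median -0.24, 6 adjusted over the list alone). Among them Tnfaip3 (189 ± 28.6 and 131 ± 20.2 CPM), Nfkbia (2196 ± 316 and 1590 ± 205) and Nfkbiz (534 ± 153 and 308 ± 43.7) passed over all genes. The call of Nfkbia held in 11 of 13 alternative settings and in 19 of 24 fits with 1 mouse left out. Cholesterol synthesis genes were higher, with a median of 0.17, and 6 higher and 1 lower adjusted over the list alone. Among them Cyp51 was at 0.40 and Msmo1 at 0.23. Late DAM genes were higher by a median of 0.17, with Serpine2, at 278 ± 34.2 and 474 ± 183 CPM, passing over all genes and 2 adjusted over the list alone. The call of Serpine2 held in 10 of 13 alternative settings and in 16 of 24 fits with 1 mouse left out. Early DAM genes were higher by 0.12, in 10 of 10. MHC class II genes had a median of 2.42, or 1.22 with the replicate block, and did not pass, with 4 adjusted over the list alone. The level of MHC class II genes moved with R47H induced mouse 5, in which 16.5% of microglia-like cells were MHC II-high. Mitochondrially encoded genes passed only with the block (-0.11).

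Control mice of both lines, which had not received tamoxifen, give the difference between the lines without induction. In control mice 140 genes were higher and 160 lower in R47H, out of 1751 with an unadjusted p under 0.05. Ccdc80 was again higher, at 2.55 ± 1.32 and 26.3 ± 8.59 CPM (3.38, SE 0.30, adjusted p = 5.0e-07), and the kinase gene Cdk14 was at 9.74 ± 1.21 and 27.7 ± 5.07 CPM (1.504, SE 0.13, adjusted p = 1.9e-07). Slamf8 (12.3 ± 2.63 and 87.8 ± 18.3 CPM), Igsf8 (48.8 ± 3.95 and 146 ± 25.6) and the Fc receptor gene Fcgr4 (7.05 ± 1.27 and 19.5 ± 10.5) were higher. So were Fam167b (1.35), Fgl2 (1.35), Oser1 (1.43), Ralgps2 (1.31) and the sialomucin gene Cd34, at 67.7 ± 23.8 and 165 ± 45.9 CPM. Pttg1 was lower, at 29.5 ± 4.08 in WT and 5.75 ± 2.52 CPM in R47H mice (-2.36, SE 0.42), as was F11r, at 440 ± 16.03 and 222 ± 49.5 CPM (-0.99, SE 0.11, adjusted p = 9.5e-06). Uap1 (39.1 ± 3.75 and 20.1 ± 3.88 CPM), Olfml2b (-1.19), Upk1b (-1.86), Cbr3 (-1.45), Pcp4 (-1.60), Ccdc66 (-0.95), Rgs7bp (-0.91) and B4galt4 (-0.89) were also lower.

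Late DAM genes were higher in R47H control mice, with a median of 0.57 and 31 of 32 above 0 (camera adjusted p = 8.3e-09, and 0.840 with an estimated correlation). Slamf8, Ctsl (985 ± 185 and 1655 ± 356 CPM), Serpine2 (330 ± 52.1 and 618 ± 98.3 CPM) and Cadm1 passed over all genes, and 9 adjusted over the list alone. Early DAM genes had a median of 0.24 and lysosome genes of 0.09. Immediate early genes were lower (median -0.23, 5 adjusted over the list alone), with Junb at 4531 ± 288 and 3475 ± 430 CPM and Ier2 at 1383 ± 204 and 983 ± 111 CPM passing over all genes. Here too the part of dissociation was not tested. Interferon genes were higher by a median of 0.75, in 33 of 34, with Ifi44 and Rsad2 passing. Respiratory chain genes (0.12, with Sdhc lower by 0.23), ribosomal protein genes (0.14), MHC class I genes (0.44) and MHC class II genes (2.32) passed as well. Cd74 was at 115 ± 111 CPM in WT and 574 ± 749 CPM in R47H control mice. The interferon and MHC lists moved with R47H control mice 4 and 6, in which 21.7% and 8.64% of microglia-like cells were MHC II-high. Without R47H control mouse 4 and R47H induced mouse 5 the calls of Rsad2 (1.69, adjusted p = 0.0835), Cadm1 and Pcp4 ended. In that fit, which kept R47H control mouse 6, the interferon median was 0.34 and still passed, and the MHC class I (0.16) and class II (1.27) medians did not. The summed B-cell markers in the same cells were at 388 ± 68.1 CPM in WT and 824 ± 544 CPM in R47H control mice (two-sided exact permutation p = 0.160, adjusted p = 0.948), and monocyte markers at 371.5 ± 81.1 and 509 ± 208.5 CPM. No marker sum of another cell type passed in any contrast (smallest adjusted p = 0.364).

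The line differences with and without induction were set side by side. Of the 309 and 300 calls, 128 were shared, 56 higher and 72 lower in R47H, against 7.15 expected, and no gene passed in opposite directions. The log2 fold changes had r = 0.747 across 12969 genes, which are not independent replicates, and no sample is in both comparisons. A stretch of chromosome 14, 3030002-12303231, held 22 of the induced and 24 of the control calls among 41 tested genes, many of them near-identical predicted genes, against at most 15 and 17 in random sets.

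**Figure D3:**
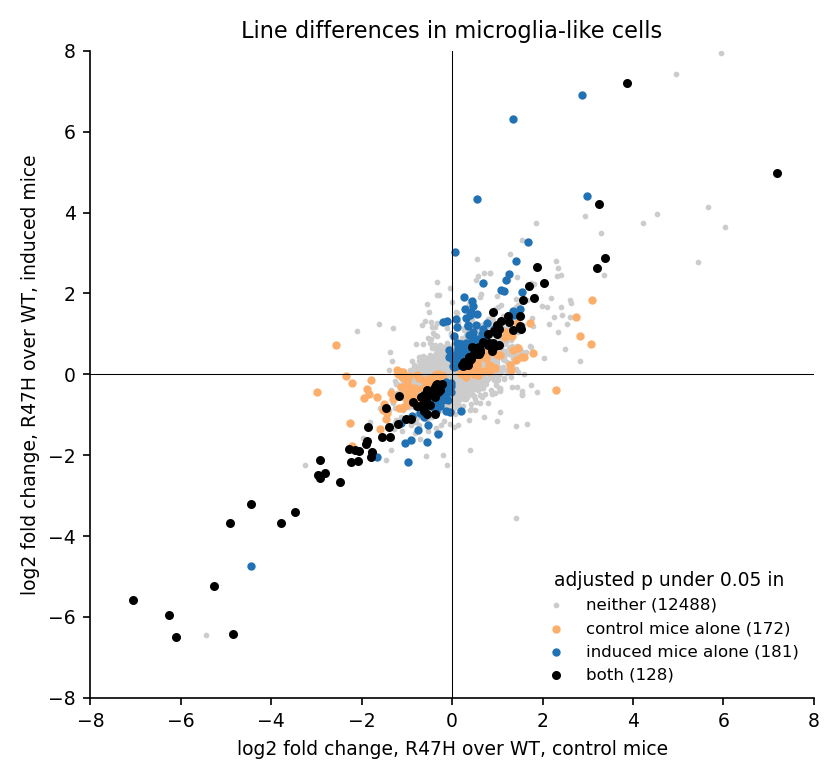
Log2 fold change of R47H over WT microglia-like cells in control mice (x axis) against induced mice (y axis), 1 point per gene, coloured by where it passed (128 genes in both, 172 in control alone, 181 in induced alone, 12488 in neither; 8 genes lie outside the frame). Genes passing in both lie along the diagonal.

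The other cell classes were tested to see which changes were limited to microglia. With WT induction 3 calls were made over 9 classes. Sp100 rose in pericyte-like cells from 7.70 ± 5.48 to 38.3 ± 7.61 CPM (2.15, SE 0.39, adjusted p = 0.00894), Rpgrip1 fell in astrocyte-like cells (-3.94), and Gm26632 fell in smooth muscle-like cells (-2.11). With R47H induction 35 calls were made in 29 genes, 23 of them on chromosome 1. In astrocyte-like cells 11 genes rose and 4 fell. Pttg1 rose from 1.44 ± 0.117 to 54.5 ± 48.7 CPM, in 5 of 6 mice, Rgs7 rose from 41.8 ± 5.89 to 64.5 ± 9.65 CPM and Vangl2 from 19.9 ± 1.19 CPM by 0.38. Fam69c (-0.45) and Map2 (-0.32) fell. In endothelial-like cells 5 genes passed, with Pttg1 (3.99, in 4 of 6 mice) and Dusp23 (29.3 ± 6.70 to 56.2 ± 9.49 CPM) higher and Kansl1l (-0.63) lower. Pericyte-like cells had 7 calls, all 7 on chromosome 1 and 2 of them in the stretch 168119364-173599274. They included the interferon-inducible genes Ifi211 (1.65 ± 2.65 to 24.3 ± 7.29 CPM), Ifi204 (5.46 ± 5.08 to 44.2 ± 17.3 CPM) and Mndal (46.3 ± 35.5 to 206 ± 36.6 CPM). Whether they rose by position or by an interferon response was not tested. Igsf8 fell there by 0.66 and rose in neuroblast-like cells by 0.78, where Aim2 rose by 1.95. Ependymal-like cells had 4 calls, including Pttg1 (2.198), which was higher, and Nxpe4 (-2.38) and Tagln2 (-0.61), which were lower. Mndal rose in smooth muscle-like cells (2.98), and Ifi203 fell in border macrophage-like cells from 450 ± 95.1 to 191 ± 46.5 CPM. Oligodendrocyte precursor-like and T-cell-like cells had no call in edgeR. For R47H induction 366 of 10932 and 124 of 2870 genes had an unadjusted p under 0.05, in both fewer than chance alone gives. Over the 9 classes DESeq2 called 29 with WT and 70 with R47H induction.

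Setd5 was also measured in the other classes. Its log2 fold change in astrocyte-like cells was 0.02 with WT and -0.02 with R47H induction, and in endothelial-like cells 0.05 and -0.05. In border macrophage-like cells, which also express Cx3cr1, it was 0.89 with WT induction (adjusted p = 0.0586) and 0.57 with R47H induction, neither passing. All 9 of these classes had calls between the lines in induced and in control mice, with 141 calls in astrocyte-like and 80 in endothelial-like cells of induced mice, and 118 and 53 in control mice. Of the 128 genes that differed between lines in microglia both with and without induction, 94 were tested in astrocyte-like cells, where 10 passed in induced and 11 in control mice, 9 and 10 of them in the direction seen in microglia. In endothelial-like cells 84 were tested, and 12 and 8 passed, all in that direction.

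Cell composition was compared to see whether a class grew or shrank. Microglia-like cells made up 47.1 ± 6.55% of WT control, 46.4 ± 4.32% of WT induced, 50.8 ± 3.32% of R47H control and 51.2 ± 5.49% of R47H induced cells (SD, n = 6). Astrocyte-like cells made up 31.3 ± 5.32%, 30.8 ± 3.50%, 25.97 ± 2.21% and 23.5 ± 3.96%. Their share was lower by 7.29 percentage points in induced R47H than in induced WT mice (two-sided exact permutation p = 0.0173, adjusted p = 0.519 over classes and contrasts). That test did not pair the mice by title set. No class passed, and no difference of inductions did (smallest permutation p = 0.0612, for neutrophil-like cells, adjusted p = 0.887). Unnamed clusters held 0.806% to 1.14% of cells in the group means. Dissociation, myelin removal and dead cell removal may influence these shares, which was not tested. Within microglia-like cells, cluster 0, with high Gpr84, Il1a, Nfkbiz and Tnf, made up 31.02% and 32.5% in WT control and induced mice and 17.3% and 18.2% in R47H mice. Cluster 4, with high Rgs1 and P2ry12, made up 12.6%, 13.97%, 21.1% and 22.9% in the same order. Cluster 10, with Cst7, Lpl, Itgax and Csf1, made up 5.41 ± 3.66% and 2.58 ± 1.22% without and with WT induction, and 6.72 ± 6.04% and 2.82 ± 1.29% without and with R47H induction. Single control mice ranged from 1.48% to 11.08% in WT and from 1.10% to 16.75% in R47H. Cluster shares were chosen for description after they were seen, and were not tested.

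**Figure D4:**
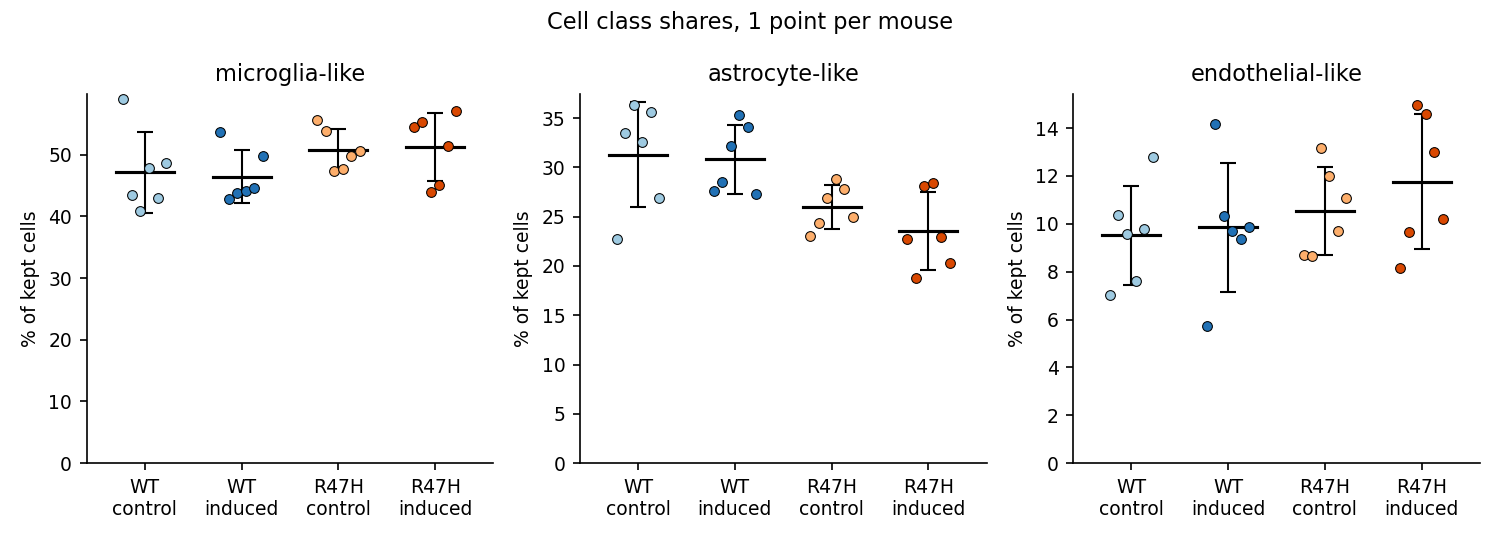
Percent of kept cells per mouse (points) that were microglia-like, astrocyte-like and endothelial-like, with the mean and SD by group (n = 6). The groups overlap in all 3 classes, and astrocyte-like shares are lowest in R47H induced mice.

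Whether the list changes rested on few cells was asked with cells high in a list, after thinning each cell to 1000 UMIs. Late DAM-high cells made up 4.09 ± 2.66% of WT control and 1.97 ± 0.686% of WT induced microglia-like cells (exact two-sided permutation p = 0.0844), and 5.35 ± 3.62% and 2.56 ± 0.981% in R47H mice (exact permutation p = 0.115, adjusted p = 0.459 for both). Mice were not paired by title set in these tests. Without thinning, where a cell was high by the percent of its UMIs in the list, the differences were -2.15 and -3.10 percentage points. With thinning they were -2.12 and -2.79. Interferon-high cells made up 1.72%, 1.81%, 3.63% and 2.42% in WT control, WT induced, R47H control and R47H induced mice, and MHC II-high cells 1.94%, 1.43%, 7.06% and 4.05%. No comparison of these shares passed. Thinning left out 147, 66, 58 and 94 shallower cells of the groups in the same order.

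**Figure D5:**
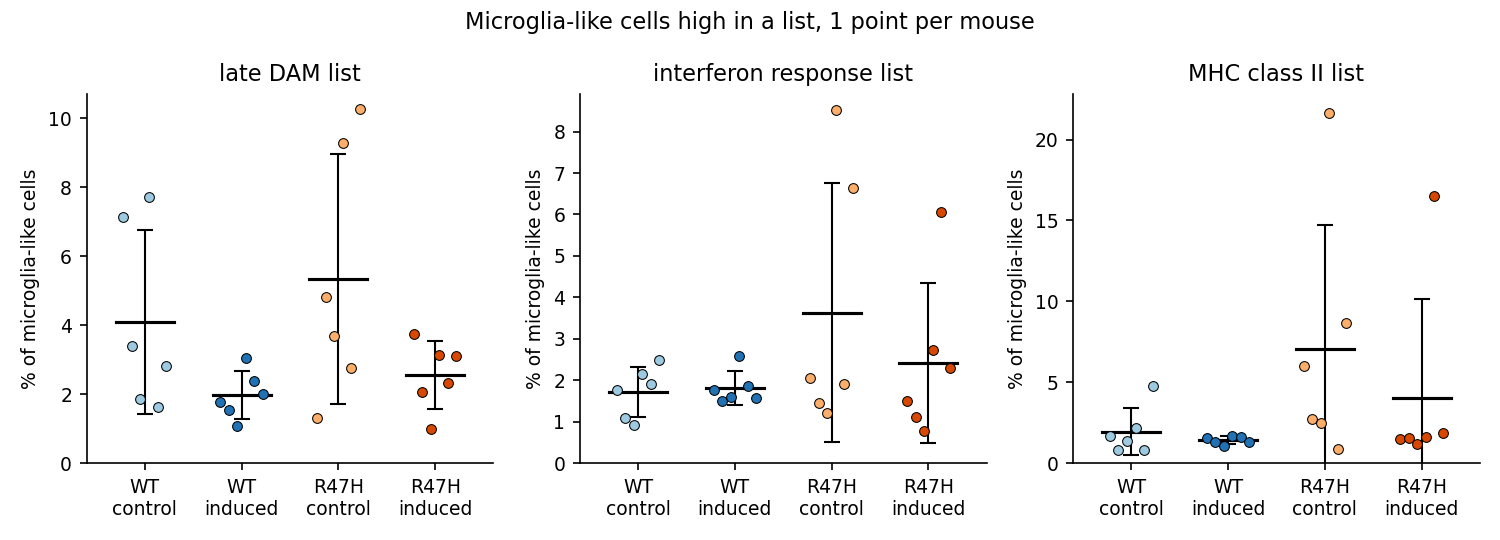
Percent of microglia-like cells per mouse (points) that were high in the late DAM, interferon and MHC class II lists after thinning to 1000 UMIs, with the mean and SD by group (n = 6; SD bars that would reach below 0 end at the axis). Late DAM-high means are 4.09% and 1.97% in WT mice and 5.35% and 2.56% in R47H mice, and R47H control mouse 4 stands apart at 21.7% MHC II-high.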

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

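The tests of position along the chromosome, the count of chromosome 1 genes changed in astrocyte-like cells, the 32 splits by title set and the intervals of count ratios were chosen only after the results they weigh had been seen. Single mice stood far from the other 5 of their group, by a test on the gap to the nearest mouse, in 21 of 176 groups of values (11.9%), where chance gives about 1 in 20. In WT control mice these were 4.745% MHC II-high cells and 17.5 CPM of Nbea in mouse 6, 50220 CPM of Cst3 in the same mouse, and 19.8 CPM of Pqlc1 in mouse 3. In WT induced mice they were a T-cell-like share of 1.135% and 52.3 CPM of Nit1 in mouse 1, and 2.586% interferon-high cells in mouse 4. In R47H control mice they were an oligodendrocyte precursor-like share of 4.081% and 23.2 CPM of Olfml2b in mouse 2, 21.66% MHC II-high cells and 16.8 CPM of Nbea in mouse 4, 14.9 CPM of Ccdc66 in mouse 3, 19.6 CPM of Zfp992 in mouse 5 and 30.3 CPM of Dedd in mouse 1. In R47H induced mice they were a median of 3.99% mitochondrial UMIs in mouse 2, and a neuroblast-like share of 5.221% and 141.8 CPM of Setd5 in mouse 1. R47H induced mouse 5 stood apart in 4 values, with a T-cell-like share of 1.514%, 6.052% interferon-high and 16.52% MHC II-high microglia-like cells, and 54.6 CPM of Atf6.

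The induction effect differed between the lines, by the test of the difference in edgeR, for 5 genes outside microglia. In astrocyte-like cells Apoa2 differed by -4.781 (log2, WT minus R47H). Its size is uncertain, since R47H control mice held 1 count, in 1 mouse, and R47H induced mice 37 (ratio 40.9, exact 95% interval 6.89 to 1657, counting error only), against 60 and 57 in WT control and induced mice. In pericyte-like cells Ifi211 differed by -3.028, with 3 and 57 counts in R47H control and induced mice (ratio 17.1, interval 5.57 to 85.4), Ifi204 by -2.244, Ifi203 by -1.341 and Pcp4l1 by -0.945. All 5 genes lie on chromosome 1.

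Setd5 and Thumpd3, on both sides of Gt(ROSA)26Sor, were higher in induced microglia-like cells. An effect of tamoxifen on cells of every class is argued against by astrocyte-like cells, where the mean Setd5 change of both inductions was 0.00327 (SE 0.0511), below 0.403, which is 50% of the change in microglia-like cells. In border macrophage-like cells, which also express Cx3cr1, it was 0.730 (SE 0.120), close to 0.81 in microglia-like cells, which is consistent with a change at 1 locus in cells with active Cre. The transgene may therefore have been inserted at this locus and switched on in both lines. Reads that run from the transgene into Setd5, and an effect on Setd5 itself, stay open and were not tested.

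R47H induction calls lay together on chromosome 1, and a spread over the genome by chance is argued against by the share of random gene sets with as many in a window, 0.0001, the smallest that the draws can give. The induced R47H receptor acting on these genes in microglia, as the whole cause, was weighed in astrocyte-like cells. By the first bound, the lower end of the median change there had to lie above 0.30, 50% of the microglial change. It was -0.11, so this bound did not exclude the receptor. A count added after those values were seen argues against it: 9 of the 12 window genes tested had an unadjusted p under 0.05 against 0.489 expected. Of these 7 changed in the microglial direction and Igsf8 (0.18) and Tagln2 (0.53) against it, and neighbouring genes are not independent, but Copa (0.37) and Cfap126 (1.56) passed there over all genes tested. Inherited sequence differences present in every cell stay open: the median change in astrocyte-like cells, in the direction seen in microglia-like cells, was 0.188, and its range of -0.11 to 0.49 holds 0.30, 50% of the microglial change. Of the window genes, Igsf8 (1.58), Slamf8 (2.83), F11r (-0.99), Uap1 (-0.96) and Olfml2b (-1.19) differed between the control lines (R47H over WT), without tamoxifen. Each of these went opposite to its change with R47H induction. They were among the largest changes, and the other window genes were not set side by side. The R47H groups may thus differ in the strain sequence near 1:168119364-173599274, with R47H induced mice mixed in Igsf8. For the window as a set this cannot be told apart from an effect of smaller size with these values.

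Late DAM genes were lower in induced mice of both lines. A difference in depth between the groups is argued against by thinned cells, in which the drop in late DAM-high cells kept at least 89.8% of its size. Chance was not excluded for the list: 21 of 100 splits of the WT mice gave a median as far from 0 as -0.37 (farthest other -0.61), as did 6 of the 32 splits that part all sets of title numbers (farthest other 0.48), and 18 of 100 splits of the R47H mice as far as -0.65 (farthest other 1.10). Nor was it for early DAM genes (5 of 100 and 4 of 32 splits as far as -0.21 in WT mice, farthest others both -0.25, and 9 of 100 in R47H mice). For lysosome genes 4 of 100 splits of the WT mice were as far as -0.13 (farthest other 0.15), and only the real one of the 32 (farthest other -0.0957). In R47H mice 5 of 100 were as far. These shares were not adjusted over the 23 lists. With fry and the replicate block the lysosome list did not pass in WT induction (adjusted p = 0.322), so chance was not excluded for it either. The drop in late DAM genes may then come from differences in DAM level between mice that have nothing to do with induction. An effect of the transgene, tamoxifen or Cre stays open as untested.

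Other splits of the same mice into groups of the same size were used to ask whether chance gives as many calls. For WT induction only the real split of 100 reached 22 calls (highest other 10), and among all 32 splits that part every set of title numbers again only the real one did (highest other 10). Likewise 1 of 100 splits reached the 37 calls of R47H induction (highest other 6), the 309 of the induced line comparison (highest other 16, among 12 others parting all sets 16) and the 300 of the control line comparison (highest other 33). This argues against counts that any split of these mice would give, at a share of 1 in 100, the smallest these draws can show. It cannot tell induction or line from other differences between the mice of the groups. For the difference of inductions all 100 splits reached the 0 calls, as any split must, so this decides nothing. In 1 split 444 genes were called (next 4), and what sets this split apart was not tested. In the other classes, 7 of 21 splits reached the 3 calls of WT induction (highest other 613, next 16, the reason for the 613 not tested), so chance was not excluded, while 1 of 21 reached the 35 calls of R47H induction (highest other 9).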

How the results depend on the processing

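The fit without R47H control mouse 4 and R47H induced mouse 5 and the average of both inductions were chosen after the data were seen. The cause of a changed count was not tested unless a clause says otherwise. Calls in microglia-like cells, 22, 37, 0, 309 and 300 for WT induction, R47H induction, their difference, the induced and the control line comparison, became 52, 84, 14, 467 and 502 with DESeq2. With genes of at least 10 CPM in 6 samples, which are fewer genes tested, WT induction had 12, the difference 1 and the control lines 188. With only the groups of the contrast, which are fewer samples, R47H induction had 11 and the control lines 180. With the replicate block R47H induction had 85, the difference 3, the induced lines 579 and the control lines 639. Without R47H control mouse 4 and R47H induced mouse 5, R47H induction had 24, and the calls of Hjurp, Pqlc1, Olfml2b, Slc29a3, Dedd and Cnn2 ended. The difference had 2 calls without a low-count filter and 1 without doublet removal. Other classes went from 3 calls with WT induction to 29 with DESeq2, 15 without the filter and 6 with the replicate block, and from 35 with R47H induction to 70, 87 and 59.

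Gene lists passing, 5, 9, 7, 5 and 9, all became 0 with an estimated correlation, where the late DAM medians of -0.37 and -0.65 had an adjusted p of 0.840. With the stricter cell filter the difference had 4 lists in place of 7, and the change of microglia-like share with R47H induction went from 0.376 to -3.14 percentage points. Trem2 between induced lines, 0.10, ranged from -0.0022 without R47H induced mouse 1 to 0.17.

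With 1 mouse left out, calls ranged from 9 (without WT induced 3) to 27 for WT induction, with 13 without WT control 1 and 12 without WT induced 6. They ranged from 19 (without R47H induced 6) to 45 for R47H induction, with 24, 24 and 21 without R47H control 3, 5 and 6, and 23 and 21 without R47H induced 3 and 4. For the difference they ranged from 0 to 9 (without R47H control 2), with 7 without WT control 3, 2 without R47H induced 1, and 1 without WT control 2 or R47H control 5 or 6. They ranged from 227 to 325 for the induced and 215 to 318 for the control lines. Lists passing ranged from 5 to 8 (without WT control 4), 5 (without R47H control 4) to 14 (without R47H induced 5), 2 (without R47H control 4) to 9, 4 to 8 (without R47H induced 2 or 3) and 5 (without R47H control 4) to 12, with 4 for the difference without WT control 3, R47H control 6 or R47H induced 2. The late DAM median ranged from -0.44 to -0.23 in WT and -0.95 to -0.44 in R47H induction, and the share of late DAM-high cells changed by -2.61 to -1.40 and -3.59 to -1.80 points. The microglia-like share changed by -2.11 to 1.71 points in WT (1.71 without WT control 1, 0.0773 without WT induced 2) and by -0.785 to 1.82 in R47H mice, with -0.312 and -0.242 without R47H control 3 and 4, and -0.270, -0.445 and -0.785 without R47H induced 1, 2 and 6.

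Of list medians, 364 kept their side of the threshold under the settings and 57 lost it, and with 1 mouse left out 723 and 69. Of named genes, 1023 and 73, and 1828 and 211, did so, with 1 reversed. Named genes that passed did so under every setting in 3 of 8, 4 of 20, 15 of 24 and 22 of 28 cases for WT induction, R47H induction, induced and control lines, and with every mouse left out in 4, 10, 16 and 24. In WT induction and the induced lines the replicate block ended the calls of Ang, Liph, Iglc1 and Rnase6, added that of mitochondrially encoded genes, and changed no other call of a list or of a named gene that had passed. In the other contrasts it ended the calls of Pqlc1 with R47H induction and Rsad2 between control lines, which a sex term ended too, and proliferation genes passed with it in the difference (-0.64) and between control lines (-0.65). In R47H induction it moved the MHC class II median from -0.52 to -1.32 and the proliferation median from -0.21 to -0.0181. With 1 mouse left out, Hjurp, Dedd and Slamf8 passed in R47H induction in 13 of 24 fits. Genes under 10 CPM and classes with few cells limit what could be called at this depth.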

Other observations

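The contrast that averages both inductions was chosen after the results were seen, and the list tests in other classes were planned. Averaged over both lines, 40 genes were higher and 61 lower with induction in microglia-like cells, and 105 and 129 with the replicate block. Setd5 changed by 0.81 (SE 0.05), Slc29a3 by 0.45, Thumpd3 by 0.37, Cst3 by -0.32, Vangl1 by -0.85, Loxl3 by -0.94 and Dlc1 by -1.03. Late DAM genes had a median of -0.52 (camera adjusted p = 5.0e-19, and 0.218 with an estimated correlation). Early DAM genes had a median of -0.24 and lysosome genes of -0.15, and neither passed with an estimated correlation (adjusted p = 0.218 for both, and 0.264 for all 3 lists with the block). With fry the lysosome list passed with the block (adjusted p = 0.0475) and not without it (0.0693).

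In astrocyte-like cells the interferon list was higher with WT induction (median 0.29 over 24 genes, 2 adjusted over the list alone), as were cholesterol synthesis genes (0.12). Ribosomal protein genes were higher with WT and R47H induction in astrocyte-like (0.08 and 0.10) and endothelial-like cells (0.16 and 0.08). Endothelial-like cells had higher MHC class I (0.41) and endothelial activation genes (0.35, 2 of 10 adjusted over the list alone) with R47H induction. Glycolysis genes were lower in astrocyte-like cells of R47H than of WT control mice (-0.18, 7 adjusted over the list alone). No list of these classes passed with an estimated correlation, where the smallest adjusted p was 0.280 in astrocyte-like and 0.137 in endothelial-like cells. Gt(ROSA)26Sor, named after its values were seen, was at 6.81 ± 4.85 CPM without and 16.1 ± 8.97 CPM with WT induction in microglia-like cells, and at 4.41 ± 2.45 and 9.65 ± 4.68 CPM in R47H mice. It passed in neither contrast, nor averaged over both lines, but did so in that average with the replicate block (1.27, adjusted p = 7.1e-05 in edgeR).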
